A study of Homo sapiens with 6 samples.

How the data were processed

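RNA of HSC-3, a cell line from a human tongue squamous cell carcinoma, was measured on 6 Affymetrix oligonucleotide arrays. Per the labels, 3 arrays carried RNA of cells made to overexpress trypsin-2 and 3 carried RNA of cells with a control vector, all harvested after 48 h of culture. Labelled cRNA was made from 2 µg of total RNA per array, per the labels' protocols. Groups and replicate numbers 1 to 3 were taken from the sample titles. Nothing in the labels says that replicates of a group were separate cultures, so p-values measure only the spread between these samples, which may be technical. Those from shuffled gene orders and random draws of genes hold no spread between arrays at all.

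The deposited values are intensities, 1 linear signal per probe set and array, made with MAS5 per the submitters' processing notes, with the version not given in the sources used here. On each array the mean of the signals between percentiles 2 and 98 was 100 within rounding (99.98 on each array), so the authors' scaling was kept. The signals of the 6 arrays ran from 0.0142 to 12091, with array medians of 14.7 to 17.5. Presence calls were not used here. Of 54675 probe sets, 62 are controls. The platform annotation gave 41097 probe sets 1 gene symbol, 1801 several and 11777 none. Of those with 1 symbol, 41043 were matched by gene identifier to a reference gene table of assembly GRCh38.p14, and 54 kept the name given. Probe sets with several symbols name no gene, except where a trypsinogen probe set is reported as such.

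Signals were transformed as log2(signal + 16), so every fold change is on that scale and understates the change of dim probe sets. Probe sets were tested where their mean over the 6 arrays reached the median of the 54613 non-control probe sets (4.96 on the log2 scale, a signal of 15.2), which left 27307. The comparison of overexpressing with control vector was fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), with group as the only term, and adjusted by Benjamini-Hochberg at 0.05 with no fold minimum. Each of 12151 genes was represented by its probe set of highest mean. Single measures were compared by exact two-sided permutation tests, which with 3 arrays against 3 cannot go below p = 0.1.

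The gene lists numbered 23 and held the trypsinogens, tight junction, adherens junction and desmosome, matrix metalloproteinases and ADAM proteases, other serine proteases with their inhibitors, kallikreins, protease-activated receptors, NF-kB targets, keratinocyte differentiation, basal and hemidesmosome genes, simple epithelial keratins, epithelial to mesenchymal transition, fibroblast and leukocyte markers, proliferation, interferon response, unfolded protein response, hypoxia and glycolysis, cholesterol synthesis, EGFR and MAPK genes, integrins, NRF2 targets and p53 targets. Of 512 list places, 39 had no probe set with a single symbol on the array. Lists with at least 3 tested members, 21 in number, were tested with camera at a preset correlation of 0.01 between genes and adjusted over lists. The same test with an estimated correlation, and limma's fry, were run beside it.

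The samples, groups, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. That rule names every trypsinogen probe set. It names up to 10 genes of largest rise and 10 of largest fall among called genes with no overlap between the groups. Their higher group mean had to be at or above the filter level. The rule as fixed did not mention the replicate block. Its use on the blocked fit as well, for these genes and for list members, was an extension of it. It also names up to 4 called members of each list by size, or, from a list with no called member, 2 members of smallest p. Genes named outside the rule are said to have been chosen after their values were seen.

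Replicate numbers in the labels were checked for pairing before calls were compared. Over the tested probe sets, the deviations of same-numbered arrays from their group means correlated with r = 0.64, 0.39 and 0.25 for numbers 1, 2 and 3. Each was over 0.1, and on that ground the numbers were used as a block. Differently numbered arrays passed 0.1 too, with 0.32 for overexpressing 2 with control 3 and 0.20 for overexpressing 3 with control 2. A shift shared by both replicate 1 arrays can give such values, so they do not show that numbers 2 and 3 pair arrays. The fit with the replicate number as a block is therefore printed beside each result whose call or count it changes. The labels do not say what a number stands for.

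Alternatives were pseudocounts of 1 and 64, filters at none, the percentiles 30 and 70, quantile normalization, centring of array medians, no intensity trend of the variance, the replicate block, replicate 1 against replicates 2 and 3 as a batch factor, the mean of a gene's probe sets, probe sets of shared sequence left out, and each array left out in turn. Fits with the block under these same settings, replicates 2 and 3 alone, and lists without genes of shifted runs were added after the data had been seen. Gene order along the chromosomes came from the same reference table and was used only to say which genes are neighbours: 12114 tested genes were placed, the median log2 fold change was taken over windows of 10 neighbours, and gene order was shuffled 1000 times.

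The steps were tested on simulated arrays made from the means and replicate 1 shift of the 27307 probe sets and the residual spread of the blocked fit, with 200 changed in each of 20 draws. This spread was the one moderated by eBayes, already drawn toward the intensity trend. The rates below are therefore those of a setting that favours fits with the trend. Without the block, limma recovered on average 1.79%, 38.4% and 96.4% of log2 changes of 0.5, 1 and 2, and 0.112% of its calls were of unchanged probe sets. With the block these were 50.7%, 96.0% and 100%, and 8.66% of calls were of unchanged probe sets, above the nominal level. The block without the intensity trend recovered 1.34%, 68.8% and 99.7%, with 0.728% of calls unchanged. In the other steps camera called the 1 shifted list and none of the others, and the window scan found 3 of 3 shifted runs. The simulated noise was independent between probe sets. These steps therefore cannot show false lists or runs that arise where genes vary together. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. No array was left out.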

Results

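The series asked how trypsin-2, a serine protease made from the trypsinogen gene PRSS2, alters gene expression in HSC-3, a tongue squamous carcinoma line. Expression was measured on 3 arrays labelled trypsin-2 overexpressing and 3 labelled control vector, all after 48 h of culture. The number of arrays, 3 per group, limits the precision. Both replicate 1 arrays stood apart from the other 4: principal component 1, with 45.6% of the variance, parted replicate 1 from replicates 2 and 3, and component 2, with 21.7%, parted the groups. On the replicate 1 arrays a 28S ribosomal RNA probe set averaged 606 against 2232 on the others, and the log2 ratio of 3' to 5' signal of ACTB was 0.21 to 0.25 against 0.46 to 0.59. Between the groups, 9 measures of array quality, these included, had exact permutation p from 0.2 to 0.9 (adjusted p = 0.9 each), in a test too small for any of them to pass. The 3' to 5' ratios of both ACTB and GAPDH were lower on the array labelled overexpressing in all 3 replicate numbers, by a mean log2 of 0.03 each, against an SD within groups of 0.179 for ACTB and 0.0349 for GAPDH. These SDs include the shift of replicate 1. By number the ACTB difference was -0.036, -0.043 and -0.017 in replicates 1, 2 and 3.

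**Figure D1:**
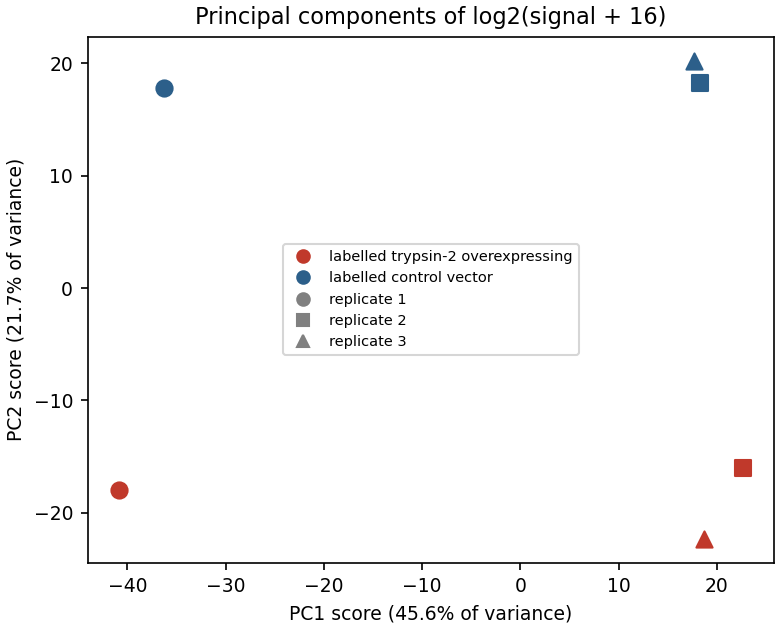
Scores of the 6 arrays on principal component 1 (horizontal, 45.6% of variance) and 2 (vertical, 21.7%) of log2(signal + 16), with colour for the labelled group and symbol for the replicate number. Replicate 1 of both groups lies at -40.9 and -36.3 on component 1, and the arrays labelled control lie at 17.8 to 20.2 on component 2, above all arrays labelled overexpressing.

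The introduced gene was read first, as a check of the labels, and its signals went against them. The brighter of 2 tested PRSS2 probe sets gave 20.4, 13.8 and 14.6 on replicates 1, 2 and 3 labelled overexpressing and 19.6, 80.8 and 83.2 on those labelled control vector. Its means were 16.3 ± 3.63 and 61.2 ± 36.0 (SD, n = 3 each), a log2 fold change of -1.12 ± 0.37 (SE), with an exact permutation p of 0.2. The dimmer tested PRSS2 probe set gave 19.1 ± 1.05 against 38.4 ± 15.9 (exact permutation p = 0.1, the smallest possible), a log2 fold change of -0.59. A further probe set, which the annotation assigns to both PRSS2 and PRSS1, gave 2.67 ± 0.771 against 1.07 ± 0.303, near the floor of the arrays and below the filter (exact permutation p = 0.1). PRSS3, another trypsinogen gene, gave 18.2 ± 6.03 and 18.4 ± 7.45 on its brighter probe set, a log2 fold change of 0.00, and 9.93 ± 2.60 and 11.1 ± 4.38 on its dimmer one, which fell below the filter. No trypsinogen probe set passed the threshold: limma gave the brighter PRSS2 probe set an adjusted p of 0.467, and 0.0506 with the replicate block, while its unadjusted p was 0.0152. Of the 2 trypsinogen genes tested 1, PRSS2, passed downward when adjusted over the list alone. Probe sets with names ending in _x_at, as those of PRSS2 and PRSS3 above the filter do, can read related sequences, and whether any of them reads the introduced one is not given in the sources used here. Every direction in the comparison therefore rests on the labels, and arrays are named by their label throughout.

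**Figure D2:**
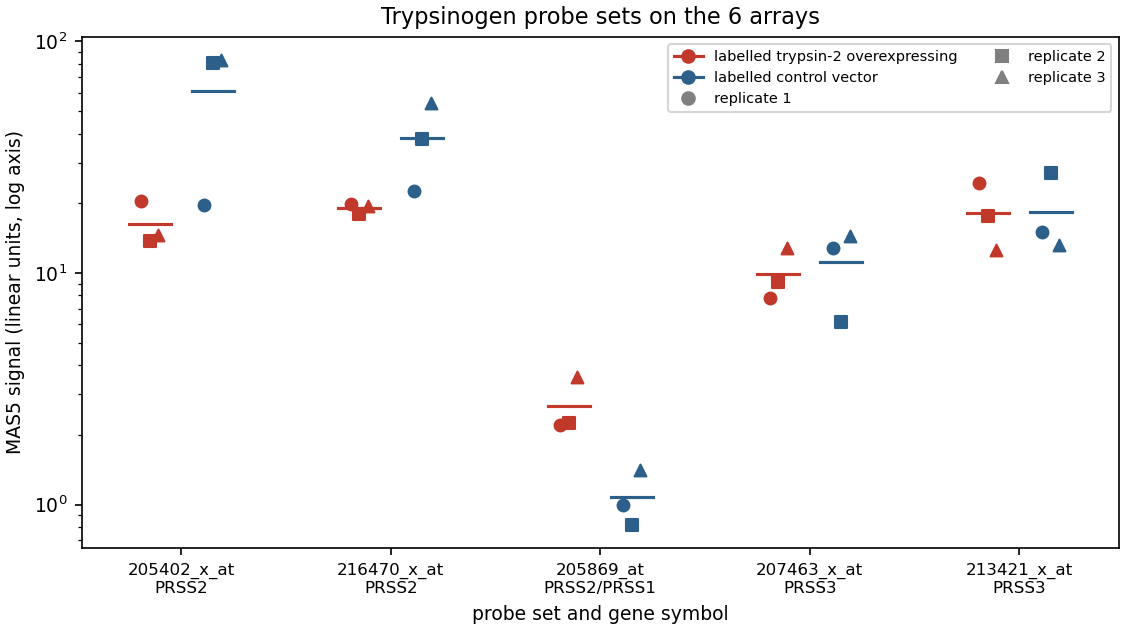
MAS5 signal (log axis, linear units) of 5 trypsinogen probe sets on the 6 arrays, with colour for the labelled group, symbol for the replicate number and a line at each group mean. For the brighter PRSS2 probe set, replicates 2 and 3 labelled control vector lie at 80.8 and 83.2, while replicate 1 with that label lies at 19.6, among the arrays labelled overexpressing.

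TUSC1, a candidate tumour suppressor, rose 3.99-fold on the arrays labelled overexpressing (log2 2.00 ± 0.16, SE, on the scale of log2(signal + 16), as all folds here), from a mean of 59.2 to 282. UGT8, which makes the glycolipid galactosylceramide, rose 3.73-fold, from 26.4 ± 7.55 to 141 ± 16.6 (SD, n = 3 each). MMP1, the interstitial collagenase, fell 2.64-fold, from 5086 ± 335 to 1947 ± 422. IL1R2, a decoy receptor of interleukin-1, fell 2.39-fold, from 269 ± 7.81 to 103.6 ± 9.84, and a further probe set of IL1R2 was also called lower. NRG1, a ligand of ERBB receptors, fell 2.23-fold on its brightest probe set, although 3 of its 4 other tested probe sets had the opposite sign. MMUT, the mitochondrial methylmalonyl-CoA mutase, fell 2.14-fold, and DCUN1D5, a factor of cullin neddylation, fell 2.05-fold. These 7 genes (2 higher, 5 lower), with 8 probe sets, were all that limma called among 12151 genes, with adjusted p from 0.0248 to 0.0386, and 1140 genes lay at an unadjusted p under 0.05. The limma count without replicate 2 or 3 labelled overexpressing, or without replicate 2 or 3 labelled control, fell to 0 genes in each case, with 838, 898, 823 and 779 genes at an unadjusted p under 0.05. It was 22 without overexpressing replicate 1. It was 11 with quantile normalization (5 higher, 6 lower), 9 with array medians centred (5 higher, 4 lower), 29 with the mean of a gene's probe sets (12 higher, 17 lower), and 4 without the intensity trend of the variance (3 higher, 1 lower).

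With the replicate number as a block, the connexin genes GJB6 and GJA1, of gap junctions, rose 2.49- and 2.44-fold, GJA1 from 248 ± 40.9 to 636 ± 151. BCHE, a cholinesterase, and IFI44L, an interferon-induced gene, each rose by a log2 fold change of 1.59. Rises of 2.36- to 2.45-fold were found for PRMT6, an arginine methyltransferase, TUBA1A, an alpha-tubulin, RASSF6, a Ras association domain protein, and MRGPRX3, a G protein-coupled receptor. The control means of IFI44L (4.02) and PRMT6 (13.5) lay below the filter level, so that their folds depend on the pseudocount. Of the genes that fell, AKR1C2 and AKR1C1, aldo-keto reductases of steroid metabolism, fell 3.56- and 2.68-fold, AKR1C1 from 1846 ± 329 to 680.1 ± 135. Their probe sets end in _x_at and can share targets. CDH2, which encodes N-cadherin, fell 3.31-fold, from 61.1 ± 35.7 to 5.37 ± 3.18, below the level of the filter. Falls of 2.50- to 2.61-fold were found for AADAC, an arylacetamide deacetylase, CRIP1, a LIM domain protein, TENM3, a teneurin, the pseudogene DUXAP10 and TMEM45A. AADAC, CRIP1, TENM3 and DUXAP10 also lay below the filter level on the arrays labelled overexpressing, with the same limit.

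The blocked limma fit called 846 genes (425 higher, 421 lower), 58 of them with an absolute log2 fold change of 1 or more, and all 7 genes of the fit without the block. In 595 of the 846 the groups did not overlap, and in the rest they did. Of the 846, 456 had a further tested probe set, and 109 of these had one of opposite direction. Within replicates 2 and 3 alone 196 genes were called, and of 1932 genes at an unadjusted p under 0.05 there, 85.8% had the same direction in replicate 1. The 846 rest on the intensity trend of the variance, without which the blocked limma fit called 0 genes, with 2042 at an unadjusted p under 0.05. In simulated data, whose spread was drawn toward that trend, 8.66% of blocked calls were of unchanged probe sets. Without a filter 270 genes were called, without replicate 1 of both groups 505 and without replicate 2 of both groups 406. All 63 named genes called with the block alone lost the call without the trend, which the count of 0 already fixes. Without a filter 28 of them lost it.

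**Figure D3:**
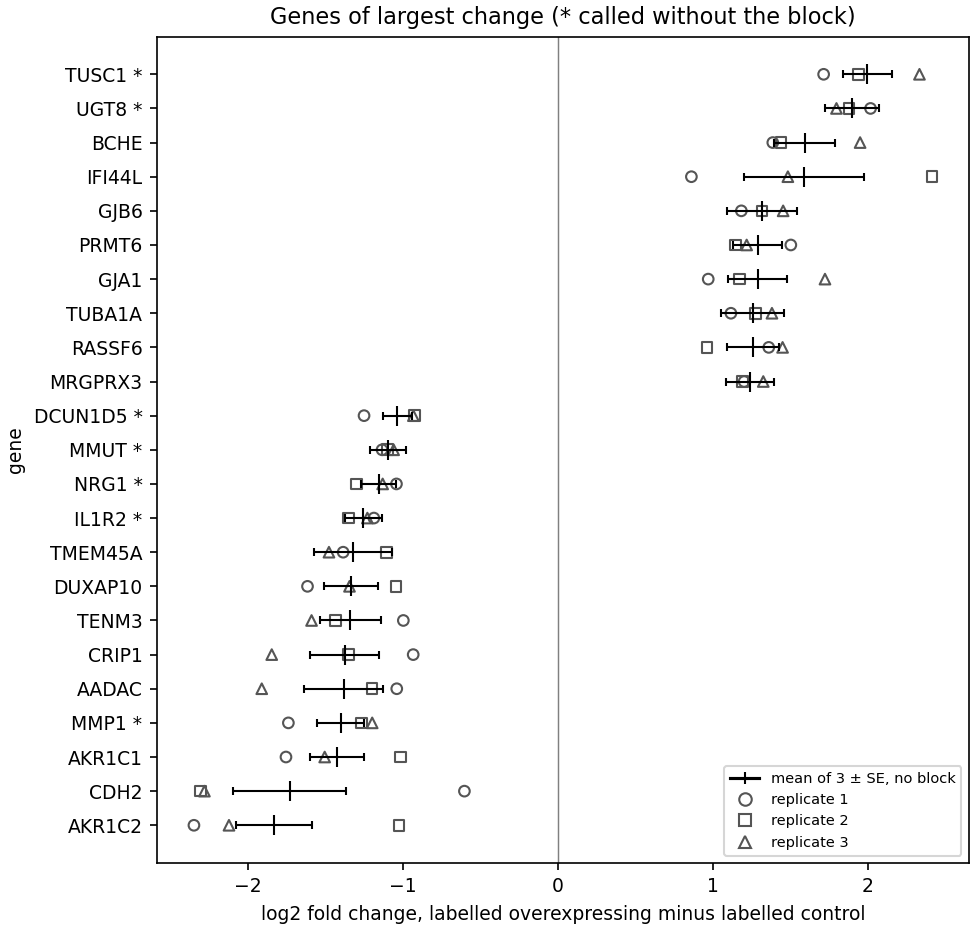
Log2 fold change (labelled overexpressing minus labelled control, log2(signal + 16)) of the genes chosen by size of change on this scale, with a bar at the mean ± SE without the block and a symbol for each replicate number. All 3 differences of each gene share a sign, from 2.00 for TUSC1 to -1.83 for AKR1C2, and an asterisk marks the 7 genes called without the block.

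Of 28 tested interferon-stimulated genes, 11 rose on the arrays labelled overexpressing and none fell with the block, among them IFI44L (log2 1.59 ± 0.26, SE), IFIT1, which binds viral RNA (1.04 ± 0.11), IFI44 (0.92 ± 0.10) and IFI27 (0.85 ± 0.09). When adjusted over the list alone 14 rose with the block and 3 without it, while limma without the block called no member over all genes, with 10 at an unadjusted p under 0.05. The list's median log2 fold change was 0.45, with 0.13 in replicate 1, 0.63 in replicate 2 and 0.52 in replicate 3. Camera called it upward (adjusted p = 9.11e-09, and 6.08e-12 with the block), but not with an estimated correlation (adjusted p = 0.488, and 0.662 with the block). Fry did not call it either (adjusted p = 0.322, and 0.147 with the block).

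Of 28 cytokines, chemokines and other NF-kB targets, 10 rose and none fell with the block, with CXCL2, a neutrophil chemokine, at 1.08 ± 0.07 (log2, SE), CSF3, the granulocyte growth factor, at 1.04 ± 0.16, IL32 at 1.04 ± 0.23 (not called with the batch factor of replicate 1, adjusted p = 0.0664) and CXCL1 at 0.81 ± 0.08. When adjusted over the list alone 13 rose and 1 fell with the block and 6 rose without it, and limma without the block called no member over all genes, with 9 at an unadjusted p under 0.05. The median was 0.26, with 0.28, 0.36 and 0.32 in replicates 1, 2 and 3. Camera called the list upward (adjusted p = 1.20e-05, and 2.32e-07 with the block), but not with an estimated correlation (adjusted p = 0.234, and 0.662 with the block). Fry did not call it (adjusted p = 0.0508, and 0.123 with the block). Of the 10, CXCL1, CXCL2, CXCL3 and CXCL8 lie close together on chromosome 4, with the uncalled CXCL6 among them, in a run of neighbours of which 18 of 21 were higher. TNF lies in another shifted run. Without run genes, camera gave the NF-kB list an adjusted p of 0.0152, and 0.00445 with the block, but not a call with an estimated correlation (adjusted p = 0.294, and 0.721 with the block).

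Of 19 targets of NRF2, the regulator of the oxidative stress response, 10 fell and none rose with the block: AKR1C2 (-1.83 ± 0.18, SE), AKR1C1 (-1.42 ± 0.11), SLC7A11, the cystine transporter (-1.21 ± 0.10), and AKR1C3 (-1.10 ± 0.10) fell most. AKR1C1, AKR1C2 and AKR1C3 are related genes, and the _x_at probe sets of AKR1C1 and AKR1C2 can share targets, so they may not count as separate members. GCLC, another of the 10, lies in the lower run of chromosome 6 that holds MMUT. In all, 10 fell with the block and 9 without it when adjusted over the list alone, while limma without the block called no member over all genes, with 9 at an unadjusted p under 0.05. The median was -0.39, with -0.43, -0.33 and -0.45 in replicates 1, 2 and 3. Camera called the list downward (adjusted p = 3.56e-11, and 5.70e-12 with the block), but not with an estimated correlation (adjusted p = 0.234, and 0.662 with the block). Without run genes camera gave it an adjusted p of 2.52e-10, and 1.33e-11 with the block, but again no call with an estimated correlation (adjusted p = 0.294, and 0.721 with the block). Fry did not call it (adjusted p = 0.0508, and 0.123 with the block).

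Of 24 tested matrix metalloproteinases, ADAM proteases and their regulators, MMP1, MMP13, a collagenase (-1.07 ± 0.21, SE), and MMP3, stromelysin (-0.96 ± 0.09), fell with the block, and MMP1 alone without it. MMP13, at 7.23 on the arrays labelled overexpressing, lay below the filter level there, so that its value depends on the pseudocount. In this protease list 6 fell and 1 rose with the block, and 3 fell without it, when adjusted over the list alone. These 3 proteases lie on chromosome 11 in a stretch of lower genes from YAP1 (-0.79) and BIRC2 (-0.83) to DCUN1D5. CASP1, in the same run, rose with the block (0.34). YAP1, BIRC2 and CASP1 were chosen after their values were seen. Camera called the list downward without the block (adjusted p = 0.0448), but not with the block (adjusted p = 0.0505), nor with an estimated correlation (adjusted p = 0.260, and 0.662 with the block). Fry called it without the block (adjusted p = 0.0267) and not with it (adjusted p = 0.123).

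Of 20 genes of epithelial to mesenchymal transition, CDH2 (-1.73 ± 0.29, SE), FN1, fibronectin (-1.25 ± 0.10), TGFB2 (-0.91 ± 0.16) and THBS1, thrombospondin (-0.56 ± 0.08), fell with the block and none rose. For THBS1, 1 of 5 other tested probe sets had the opposite sign. Adjusted over the list alone, 6 fell and 3 rose with the block, and 2 fell without it. Camera called this list downward (adjusted p = 0.0448), but not with the block (adjusted p = 0.0966), nor with an estimated correlation (adjusted p = 0.260, and 0.662 with the block). Fry did not call it (adjusted p = 0.0508, and 0.123 with the block). Other divisions of the 6 arrays into groups of 3 called up to 6 lists with camera, where the labelled groups called 5, and 3 with the block.

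**Figure D4:**
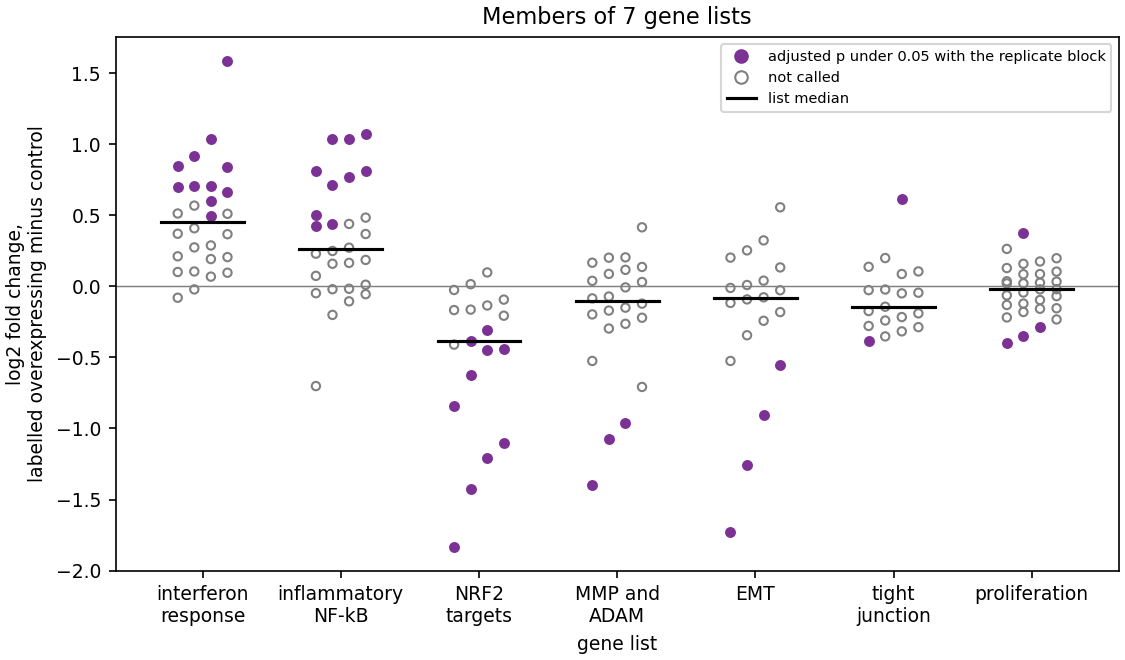
Log2 fold change (labelled overexpressing minus labelled control) of each tested member of 7 gene lists, filled where the adjusted p with the replicate block was under 0.05, with a line at the list median. Interferon and NF-kB members lie mostly above 0 (medians 0.45 and 0.26) and NRF2 targets mostly below it (median -0.39). The medians of the other lists lie nearer to 0: metalloproteinase and ADAM -0.10, transition -0.08, tight junction -0.14 and proliferation -0.02.

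Other proteases and their inhibitors went both ways. Of 25 tested, TMPRSS11E, a membrane serine protease (0.75 ± 0.16, log2 and SE with the block), HTRA1 (0.56 ± 0.11) and 1 more rose, and CST6, a cysteine protease inhibitor (-1.08 ± 0.08), and SERPINE2, an inhibitor of plasminogen activators and thrombin (-0.78 ± 0.07), fell. The groups of HTRA1 overlapped, and its SE without the block was 0.38 (unadjusted p = 0.173 in limma). Adjusted over the list alone, 4 rose and 5 fell with the block, and 2 rose and 2 fell without it (camera adjusted p = 0.409). Of 9 kallikreins limma called 0 in either fit and 0 adjusted over the list alone, with 2 at an unadjusted p under 0.05 and 3 with the block. KLK13 was at 0.53 ± 0.18 and KLK12 at 0.40 ± 0.16, and the list's median (-0.08) differed in sign from its mean (0.06) and its test (upward, adjusted p = 0.541). The other tested probe set of KLK12 had the opposite sign. The only tested protease-activated receptor, F2R, was at 0.08 ± 0.09 and was called by neither fit, nor when adjusted over the list alone. Its other tested probe set had the opposite sign.

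Of 19 tight junction genes MARVELD1 rose (0.62 ± 0.09) and CLDN7 fell (-0.38 ± 0.07) with the block, and adjusted over the list alone 1 rose and 3 fell with the block and 0 without it, with 3 at an unadjusted p under 0.05 in limma (camera adjusted p = 0.248). Of 20 adherens junction and desmosome genes CDH1, E-cadherin, fell with the block (-0.44 ± 0.08), as it did adjusted over the list alone, which called 0 without the block, with 2 at an unadjusted p under 0.05 in limma. Camera gave that list an adjusted p of 0.995, with a median of 0.003 against a negative mean and test. Among 15 integrins ITGB8 rose (0.58 ± 0.14, not called with the batch factor, adjusted p = 0.0662) and ITGB5 fell (-0.38 ± 0.09) with the block. For ITGB5, 1 of 2 other tested probe sets had the opposite sign. In total 1 integrin, adjusted over the list alone, rose and 2 fell with the block and 0 changed without it, with 3 at an unadjusted p under 0.05 in limma (camera adjusted p = 0.248).

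Among 12 keratinocyte differentiation genes, S100A8 (1.01 ± 0.25) and S100A9 (0.61 ± 0.12), which form calprotectin, rose with the block, and KRT80 (-1.15 ± 0.13), SPRR1B, a cornified envelope protein (-0.66 ± 0.13), and 1 more fell. S100A8 was at 0.62, 2.08 and 0.32 in replicates 1, 2 and 3. With the batch factor of replicate 1 in place of the block neither S100A8 (adjusted p = 0.268 in limma) nor S100A9 (adjusted p = 0.161) was called. Adjusted over the list alone, 2 rose and 5 fell with the block and 1 fell without it, and the median (0.04) differed in sign from the mean (-0.01) and the test (downward, adjusted p = 0.541). Of 11 simple epithelial markers KRT19 rose (0.56 ± 0.06) and EPCAM (-0.45 ± 0.09) and KRT8 (-0.32 ± 0.08) fell with the block. Of these markers 1 rose and 3 fell with the block and 0 changed without it, adjusted over the list alone, with 2 at an unadjusted p under 0.05 in limma (camera adjusted p = 0.418). Of 13 basal and hemidesmosome genes DST, a hemidesmosome linker, fell with the block (-0.35 ± 0.06) and lies in the lower run of chromosome 6 that holds MMUT. Of the basal genes 1 rose and 1 fell with the block and 0 changed without it, adjusted over the list alone, with 1 at an unadjusted p under 0.05 in limma. Camera gave that list an adjusted p of 0.766 downward, against a positive median (0.05), mean (0.03) and blocked test.

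Of 25 genes of the unfolded protein response, SDF2L1, an endoplasmic reticulum chaperone component (0.82 ± 0.07), XBP1, a transcription factor of that response (0.44 ± 0.07), and 2 more rose with the block, and ASNS, asparagine synthetase (-0.72 ± 0.09), and TRIB3 (-0.52 ± 0.08) fell. Adjusted over the list alone, 4 rose and 3 fell with the block, and 2 rose and 2 fell without it (camera adjusted p = 0.248). XBP1 lies in a run on chromosome 22 of which 15 of 16 genes were higher. Of 23 EGFR and MAPK genes FOS (0.74 ± 0.12), SPRY4, a feedback inhibitor (0.51 ± 0.10), and 2 more rose with the block, and FOSL1 (-0.66 ± 0.07) and DUSP4, a MAPK phosphatase (-0.62 ± 0.10), fell. The groups of FOS overlapped, and its SE without the block was 0.78 (unadjusted p = 0.374 in limma). EGFR and MAPK genes adjusted over the list alone gave 6 higher and 2 lower with the block and 1 lower without it (camera adjusted p = 0.541).

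Of 24 hypoxia and glycolysis genes ALDOC, an aldolase, rose (0.66 ± 0.15) and VEGFA, the angiogenic growth factor (-0.57 ± 0.07), HK2, hexokinase (-0.43 ± 0.08), and PDK1 (-0.37 ± 0.09, not called with the batch factor, adjusted p = 0.0932) fell with the block. Both tested probe sets of HK2 other than its brightest had the opposite sign. Adjusted over the list alone, 1 rose and 3 fell with the block and 0 changed without it, with 6 at an unadjusted p under 0.05 in limma (camera adjusted p = 0.249). Of 30 proliferation genes CDK1 rose (0.38 ± 0.08) and the mitotic kinases AURKA (-0.40 ± 0.07) and AURKB (-0.35 ± 0.08) and the replication clamp PCNA (-0.29 ± 0.07) fell with the block. AURKA lies in a run on chromosome 20 of which 10 of 11 genes were lower. Proliferation genes adjusted over the list alone gave 3 higher and 5 lower with the block and 0 without it, with 5 at an unadjusted p under 0.05 in limma (camera adjusted p = 0.541).

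Cholesterol synthesis genes, p53 targets and markers of fibroblasts and leukocytes held no member that passed limma over all genes in either fit. Among 16 cholesterol synthesis genes STARD4 was at 0.41 ± 0.15 and MSMO1 at 0.18 ± 0.09, with 0 genes at an unadjusted p under 0.05 and 1 with the block (camera adjusted p = 0.542). Among 15 p53 targets SESN2 was at -0.42 ± 0.12 and TP53I3 at 0.28 ± 0.09, with 1 at an unadjusted p under 0.05 and 3 with the block (camera adjusted p = 0.766). Markers of other cell types were a check of the culture: of 7 fibroblast markers ACTA2 was at 0.36 ± 0.11 and FAP at 0.35 ± 0.15, with 0 at an unadjusted p under 0.05 and 2 with the block (camera adjusted p = 0.273). Of 6 leukocyte markers CD14 was at 0.65 ± 0.18 and LCP1 at -0.43 ± 0.14, with 1 at an unadjusted p under 0.05 and 2 with the block (camera adjusted p = 0.542). Among leukocyte markers 1 rose and 1 fell with the block when adjusted over the list alone, and no other member of these 4 lists passed with or without it.

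Neighbouring genes shifted together in places along the chromosomes, in a scan chosen after the data had been seen. Over windows of 10 neighbouring genes, 13 runs (6 higher, 7 lower), with 225 genes, had window medians past 0.371. This limit is the 95th percentile of the largest median in shuffled gene orders of the labelled comparison. No such limit was made for other splits. The 3 other splits of the arrays that part all pairs gave largest windows of 0.358, 0.335 and 0.297, below this limit. Splits that keep both replicate 1 arrays together gave up to 0.669, which only the leading window of chromosome 11 exceeded. On chromosome 11 the window from CEP126 to DCUN1D5 had a median of -0.83, with -1.04, -0.75 and -0.80 in replicates 1, 2 and 3, and held the collagenase MMP1 and its neighbours MMP3 and MMP13. On chromosome 4 a window with the chemokines CXCL1, CXCL2 and CXCL3 and the unrelated RASSF6 had a median of 0.60, with 0.54, 0.72 and 0.68 by replicate. MMUT lies in a run of lower genes on chromosome 6, so that 3 of the 7 genes called without the block, MMP1, DCUN1D5 and MMUT, lie in shifted runs. Medians of 6 whole chromosomes had the smallest p that random draws of as many genes can give (permutation p = 1e-04, adjusted p = 0.000383). These draws take genes as independent and hold no spread between arrays, so they cannot tell a group difference from variation shared by neighbours. Chromosomes 1, 6, 15, 18 and X also had an adjusted p under 0.05 in them, chromosome 1 with a median of only -0.016. Other splits of the arrays were not tried for whole chromosomes. With the block, chromosome 20 (83.2% lower) had 78 genes called lower and 2 higher, and chromosome 16 (59.1% lower) 11 and 7. Called higher and lower were 69 and 14 on chromosome 10 (69.9% higher), 32 and 5 on chromosome 5 (68.7%), 43 and 1 on chromosome 22 (61.3%) and 19 and 8 on chromosome 19 (56.4%). The median of chromosome 19 was 0.072, 0.018 and -0.021 in replicates 1, 2 and 3, so its direction reversed in replicate 3. That of chromosome 16 was -0.007, -0.033 and -0.048. The other whole chromosomes named kept the sign of their median in all 3 numbers.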

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

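Alternatives of the fit with the replicate block, replicates 2 and 3 alone and the removal of genes in shifted runs were chosen after the data had been seen. The cause of a change was not tested except where fewer samples or genes were used.

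PRSS2, on its brighter probe set, stayed lower on the arrays labelled overexpressing and uncalled under every alternative that gave it a value, with log2 fold changes from -1.61 to -0.60 and adjusted p from 0.0506 to 0.927; leaving out 1 array gave -1.61 to -0.87. The filter at percentile 70 gave no value, since the probe set fell below it.

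Without the block, the counts of called probe sets and genes moved from 8 and 7 to 13 and 11 with quantile normalization and to 5 and 4 without the variance trend. The mean of a gene's probe sets gave 29 genes, and replicates 2 and 3 only gave 196. Leaving out 1 array gave 0 to 29 probe sets and 0 to 22 genes, with 0 genes from limma (779 to 898 at an unadjusted p under 0.05) without overexpressing 2 or 3 or control 2 or 3. Each of these fits had 1 array fewer, and the cause of the rise to 22 without overexpressing 1 was not tested.

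The replicate block gave 1424 probe sets and 846 genes, and 3 called lists in place of 5, with the metalloproteinase and transition lists lost. The batch factor of replicate 1 gave 1232, 747 and 3. With the block, no filter gave 415 probe sets and 270 genes (269 of them among the 846), and no variance trend gave 0 and 0 in limma, with 4260 and 2042 at an unadjusted p under 0.05. No replicate block gave 7 genes. Leaving out 1 replicate number gave 656 to 1511 probe sets and 406 to 866 genes. Centring array medians gave 453 genes higher and 339 lower. The block changed neither the direction of PRSS2 nor its side of the threshold.

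Without the block, 3 lists were called with a pseudocount of 1, with no filter, with no variance trend and with genes of shifted runs left out (the transition list has no gene in a run and was lost by the adjustment over lists; all 3 called metalloproteinases lie in a run, which fixed that loss), 0 with an estimated correlation (4 at an unadjusted p under 0.05) and 1 with fry. Leaving out 1 array gave 3 to 7. With the block, centring array medians gave 5 lists, an estimated correlation 0 and fry 0 (8 at an unadjusted p under 0.05), and leaving out 1 replicate number gave 4 to 7.

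The group difference of the ACTB ratio, -0.03, reversed to 0.0685 without overexpressing 1 and 0.0380 without control 3, over a range of -0.131 to 0.0685. Leaving out 1 array makes the share of replicate 1, whose ratios lay apart, unequal between the groups. Within replicate numbers 1, 2 and 3 the difference was -0.036, -0.043 and -0.017, so these reversals do not show that its sign is unstable. The uncalled gene F2R reversed to -0.00143 without replicate 2, over a range to 0.186. Of 853 alternative values of the 70 named genes that were called, 677 kept their side, 176 lost the call and 0 reversed. Of these losses 63 came from the blocked fit without the variance trend, whose count of 0 genes fixed them. Of 129 values of 11 uncalled genes, 124 kept their side and 4 gained a call.

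The smallest correlation of same-numbered arrays was 0.25, and 0.134 to 0.367 under other settings. Signals near the floor limit what can be said: fold changes of CDH2 and IFI44L depend on the pseudocount, since 1 group of each lies below the filter level, as for PRMT6, MMP13, AADAC, CRIP1, TENM3 and DUXAP10.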

Other observations

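Genes of 3 sets outside the lists, chosen after their values were seen and not tested as sets, were also read. Of 14 genes of the MHC class I pathway 8 rose with the block and none fell, with HLA-B at 0.74 ± 0.07 (log2, SE), the peptide transporter TAP1 at 0.50 ± 0.09 and the immunoproteasome subunit PSMB9 at 0.43 ± 0.07, while B2M, the class I light chain, was at 0.04 ± 0.07 and uncalled. HLA probe sets share sequence, and HLA-B and HLA-C lie in a shifted run on chromosome 6. Of 6 connexins 4 rose, GJB6 (1.32 ± 0.13), GJA1 (1.29 ± 0.12), GJB2 (0.68 ± 0.07) and GJB5 (0.33 ± 0.08). Of 7 metallothioneins, which bind zinc and copper, MT1M (1.04 ± 0.10) and MT1H (0.28 ± 0.07) rose, while MT1G (0.00) and MT2A (0.11) were among the 5 uncalled.

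The tests of gene families, of RNA integrity, of the trypsinogen signals and of single pairs behind a list were chosen only after the result was seen, as were the scan of neighbouring genes and its splits that part all pairs.

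Runs of neighbours such as the lower one around MMP1 and the higher one around CXCL1 were tested against 3 technical explanations. Chance placement is argued against by 1000 shuffled gene orders, of which none reached the largest window median (permutation p = 0.001, the smallest these permutations can give). Members of a gene family lying next to each other are argued against as the cause of every run. By the letters before a number in their names, 9 of the 13 leading windows held no family. That rule missed families in the window from TCF19 to PRRC2A on chromosome 6, counted among the 9. It held HLA-B (0.74) and HLA-C (0.49) and MICA (0.03) and MICB (-0.12), and a family cause was not tested there. In the window from CEP126 to DCUN1D5, around MMP1, it is argued against by the 6 genes outside the family, whose median of 0.811 downward passed the limit for 6 consecutive genes in shuffled orders (0.548). In the other 3 windows counted with a family, the other genes did not pass their limits. Their medians were 0.539 (chromosome 4, limit 0.702), 0.499 (chromosome 22, limit 0.505) and 0.446 downward (chromosome 20, limit 0.512). On chromosome 22 DGCR5, DGCR2 and DGCR11 were at -0.03, 0.54 and 0.19, and the whole window at 0.443. The rule grouped these genes by the letters of their names alone, which does not make them a family. On chromosome 20 CST3, CST4 and CST5 were at -0.35, 0.12 and -0.20, and the whole window at -0.431. In both, the median was larger without the genes that share letters, which argues against those genes as what carries it. For chromosome 4, where the whole window was at 0.598, a family cause stays open.

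A single pair of arrays is argued against by the smallest ratio of lowest to highest replicate median, 0.429. A copy number difference may shift neighbours together, but no DNA was measured, and this and shared regulation stay hypotheses.

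Of the 4 splits that part all pairs 1, the real one, gave a window of 0.83, and the highest other gave 0.358. That is below the limit of 0.371 that defines a run, a limit shuffled from the real split alone. Of all 10 splits 1 gave 0.83, with 0.669 the highest other. The 4 others past the limit (0.550, 0.535, 0.669 and 0.552) kept both replicate 1 arrays together. Neither 4 nor 10 splits are enough for a share under 0.05.

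The PRSS2 signals, higher on replicates 2 and 3 labelled control, were set against exchanged labels. An exchange on replicates 2 and 3 but not on replicate 1 is argued against by a correlation of 0.352 between the group differences of replicate 1 and those of the other numbers. An exchange on all 6 arrays stays open, since the highest PRSS2 difference in replicate 1 was 0.0346, near 0. That the probe sets do not read the introduced sequence also stays open: the one higher on all 3 arrays labelled overexpressing differed by 0.13, but near the floor, which excludes nothing. No biological explanation was tested.

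The higher interferon and NF-kB genes and the lower NRF2 targets were set against 3 technical explanations. For a single pair of arrays, at least 2 of 3 replicate numbers had a list median over 2 SE from 0. The second highest was 0.518 for interferon genes, 0.315 for NF-kB genes and 0.429 (downward) for NRF2 targets. For interferon genes replicate 1 was lower, at 0.133 ± 0.0909 (SE over members). This SE takes the members of a list on 1 pair of arrays as independent and holds no spread between arrays, so the test cannot decide. The medians of each list shared a sign in all 3 numbers. RNA integrity stays open: the ACTB ratio differed by -0.0322 between groups, less than its SD, but that SD includes the shift of replicate 1. ACTB and GAPDH ratios were lower on the arrays labelled overexpressing in all 3 numbers. A shift of dim against bright probe sets is argued against by quantile normalization, which kept at least 1.02 of each median. An effect of trypsin-2 stays open and untested, since the labels could not be checked.

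Other splits of the arrays were counted for the tests across genes. Without the block, 1 of 10 splits, the real one, gave 8 probe sets (highest other 1) and 1 of 10 gave 7 genes (highest other 0). With the block, 1 of 4 splits that part all pairs gave 1424 probe sets and 1 of 4 gave 846 genes, with 0 the highest other in limma for each. For lists, 4 of 10 splits gave 5 or more without the block (highest other 6), and 2 of 4 gave 3 or more with it (highest other 4). The 3 others without the block kept both replicate 1 arrays together, as the batch does, and gave 5, 6 and 5 lists, where the blocked value was 3. The remaining split of that kind, overexpressing 1 and 2 with control 1, gave 1, and whether the batch caused these counts was not tested. The number of camera calls is therefore not special to the labelled groups, and 10 or 4 splits are too few for a share under 0.05.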
